A study of Mus musculus with 12 samples.

How the data were processed

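Gene expression was measured on 12 single-channel Affymetrix arrays of RNA from mouse spleen cells sorted as Ter119-positive with high CD71, 3 arrays per genotype label, and 1 table of values per probe set and array was used. The deposited values are on a log2 scale from 1.0678 to 14.8423, with a scale inferred from the values, since on a natural or decimal log scale the highest would exceed what a scanner records. MAS5 is named as the method per the submitters' processing notes, with no version. The numeric probe set identifiers look like those of a gene-level array type, for which MAS5 is not the usual method, so it is uncertain which software made the values. The background correction and the normalization between arrays are not given in the sources used here. The table has 1 column per array, and its columns are not pooled or centred per probe set. Array medians lay between 6.22 and 6.35. The number of arrays limits the precision. No scan date or batch was given in the sources used here, and adjusted p-values reflect the spread between these arrays, which the labels call biological replicates.

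Of 35557 probe sets, 21789 carried 1 gene symbol, 1621 several and 12147 no listed gene. Symbols were brought to current names by gene number, which matched for 21698. Probe sets in the lowest 40% by mean log2 value over the 12 arrays were removed (14223, below a level of 5.84), and 21334 were kept. Probe sets with several symbols or none were left out, and for each gene the probe set with the highest mean was used, which gave 12980 genes, of which 684 had several probe sets. Among the latter, the number called with another probe set of opposite sign was 12 of 196 for E2f8 KO against WT, 7 of 293 for DKO against WT and 11 of 295 for DKO against Rb KO. Values were used as deposited, with no pseudocount and no further normalization.

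Differences were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per genotype label, all 12 arrays in 1 fit with 8 residual degrees of freedom, empirical Bayes variances with a mean trend, and Benjamini-Hochberg adjustment within each of 6 comparisons. A gene was called at an adjusted p under 0.05, and all tests were two-sided. The comparisons were E2f8 KO against WT, Rb KO against WT, DKO against WT, DKO against Rb KO, DKO against E2f8 KO, and the interaction of both labels. Of 33 lists, 23 of pathways and 10 of cell types, 32 had at least 3 measured genes and were tested with camera of limma (preset correlation 0.01, and an estimated correlation as an alternative), adjusted over the lists of a comparison. A list of embryonic erythroid genes had 2 measured genes and was not tested. Its genes are also on the globin list, so that 2 of the 3 measured globin genes are embryonic. Members were counted as changed over all genes and adjusted over the list alone. The effects of each label in both backgrounds of the other were compared by Pearson's and Spearman's correlation across genes, between comparisons with no array in common.

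The comparisons, tests, lists, thresholds and the rule for naming genes were set before the data were examined. The rule names Rb1, E2f8 and their family, the 8 largest changes each way among called genes whose groups do not overlap (5 for DKO against E2f8 KO and for the interaction, the latter without that condition), the 4 members of each list with the smallest p, and a few erythroid and cell cycle genes. The text names fewer genes than the rule allows and says where a gene was chosen after its values were seen.

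Alternatives were no filter, removal of the lowest 60%, quantile normalization, centring of each array, the mean of a gene's probe sets, all probe sets (counts only), no variance trend, array weights, only the groups compared, the replicate number as a block, other thresholds, and leaving out each array in turn. Added after the data were seen were the B cell list mean of each array as a covariate, that with the macrophage list mean, and fits without arrays that stand apart. With 1 coefficient per label, the slope on a covariate comes from differences within groups. For the B cell list these were largest in Rb KO (SD 1.15, with replicate 1 at 9.67). That slope is carried over the distance between group means, such as 10.87 in WT and 6.89 in DKO. Sizes and calls under the covariates are therefore uncertain and lean on that array. Other pseudocounts were not run, since the values are already logs, nor was a filter on probe set suffixes, since the identifiers carry none. The fit was tested on simulated data of 12980 genes per comparison, with 66 or 67 genes altered per fold change and noise drawn independently for each gene. Most comparisons of the real arrays called more genes (up to 4952), and real genes vary together. The shares and false calls below may therefore not hold for the real arrays. Of genes simulated with a 1.5-fold, 2-fold or 4-fold change, it recovered 13.4%, 70.1% and 95.5% for E2f8 KO against WT, 22.4%, 64.2% and 97.0% for Rb KO against WT, 25.4%, 53.7% and 89.4% for DKO against WT, 13.4%, 70.1% and 92.4% for DKO against Rb KO, 25.4%, 74.6% and 93.9% for DKO against E2f8 KO and 7.46%, 22.4% and 83.3% for the interaction, with 4 to 7 false calls.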

Results

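The series measured gene expression in erythroid precursors sorted from the spleens of 3-month-old mice as Ter119-positive cells with high CD71, the transferrin receptor that erythroblasts use to take up iron. There were 12 arrays in 4 genotype groups of 3 labelled biological replicates: wild type (WT), E2f8 knockout (E2f8 KO), Rb knockout (Rb KO) and the knockout of both (DKO). Rb1 encodes the retinoblastoma protein, which restrains E2F transcription factors, and E2f8 encodes an atypical E2F that represses transcription. Array medians lay between 6.22 and 6.35 on the log2 scale, and 12980 genes were tested. Replicates of a group correlated across genes with Pearson's r between 0.979 and 0.983 in WT, 0.989 and 0.991 in E2f8 KO, 0.969 and 0.990 in Rb KO, and 0.979 and 0.986 in DKO. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.184 on the log2 scale.

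Signals of the targeted genes did not follow the labels in every group. Rb1 had log2 signals of 13.02, 12.74 and 12.71 in the WT arrays, 12.53, 12.33 and 12.39 in the arrays labelled Rb KO, 11.74, 11.68 and 11.72 in those labelled E2f8 KO and 12.23, 11.98 and 12.17 in those labelled DKO. Against WT, Rb1 fell by 1.11 ± 0.11 (SE, n = 3 per group, adjusted p = 0.000154) in the arrays labelled E2f8 KO. It fell by 0.70 ± 0.11 (adjusted p = 0.000483) in those labelled DKO, while the difference in those labelled Rb KO was -0.41 ± 0.11 (adjusted p = 0.394). E2f8 had log2 signals of 12.28, 11.70 and 11.88 in WT, 12.89, 12.81 and 12.74 in E2f8 KO, 12.36, 12.52 and 11.68 in Rb KO and 13.13, 13.17 and 13.09 in DKO. It rose by 0.86 ± 0.19 (adjusted p = 0.00728) in the arrays labelled E2f8 KO and by 1.18 ± 0.19 (adjusted p = 0.000478) in those labelled DKO. Each gene was read by 1 probe set, whose position relative to the deleted part of the gene is not given in the sources used here, and a probe set outside the deleted part checks nothing. Genotype names below are therefore the labels of the arrays, and every direction drawn from them rests on those labels. Xist, the transcript of the inactive X chromosome, was at 5.22 in replicate 3 of E2f8 KO and 3.99 in replicate 3 of DKO against 11.30 to 12.18 in the other 10 arrays. The Y-linked gene Eif2s3y was at 8.17 and 7.82 in those same arrays, and both genes were chosen after their values were seen.

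**Figure D1:**
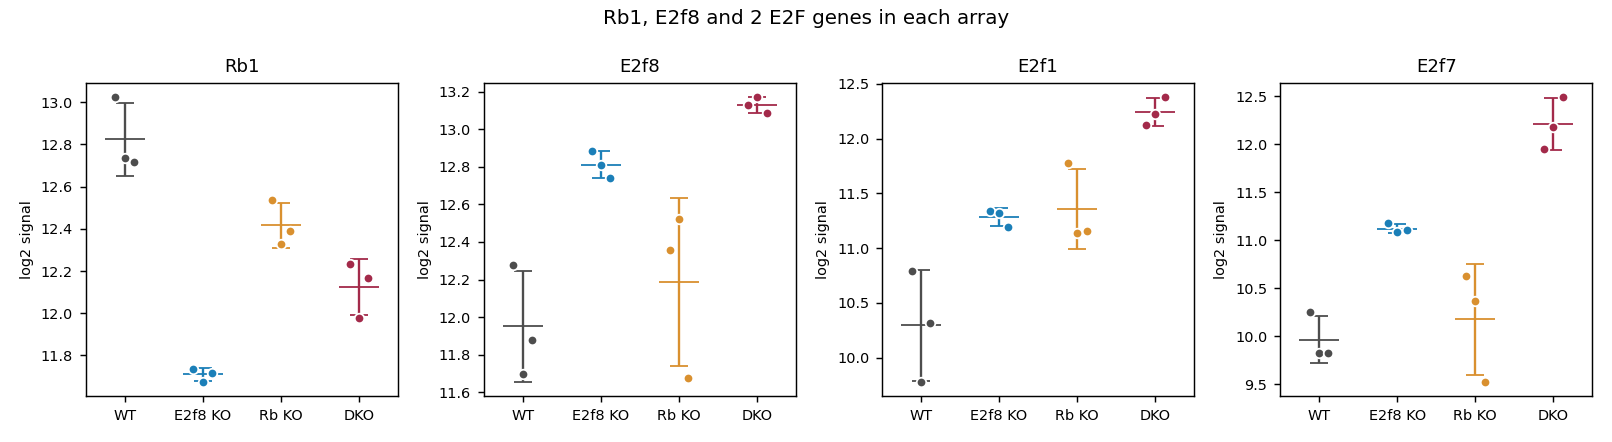
Log2 signal of Rb1, E2f8, E2f1 and E2f7 (y axes) in each array (points), by genotype label (x axes), with the mean and SD of 3 arrays as bars. Rb1 was lowest in the arrays labelled E2f8 KO (11.68 to 11.74) and E2f8 was highest in those labelled DKO (13.09 to 13.17).

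Markers of other spleen cells differed between the groups. The B cell list (15 measured genes) had a mean log2 signal of 10.87 ± 0.57 (SD, n = 3) in WT, 8.29 ± 0.15 in E2f8 KO and 6.89 ± 0.52 in DKO. Macrophage and monocyte markers (19 genes) averaged 9.22 ± 0.38, 8.45 ± 0.12, 8.09 ± 0.04 and 7.21 ± 0.36 in WT, Rb KO, E2f8 KO and DKO, and T cell markers (11 genes) 7.67 ± 0.24, 7.50 ± 0.45, 6.41 ± 0.03 and 6.04 ± 0.06 in that order. Granulocyte markers (17 genes) went the other way, from 6.26 ± 0.08 in WT and 6.73 ± 0.05 in Rb KO to 8.22 ± 0.24 in E2f8 KO and 8.22 ± 1.72 in DKO. The DKO arrays stood at 6.73, 7.84 and 10.10. The B cell list stood at 9.67, 11.67 and 11.66 in the arrays labelled Rb KO, so that replicate 1 lay apart from the others. Of the 3 B cell markers with the highest WT signal, Cd74 was at 13.13 ± 0.41 in WT and 8.59 ± 0.83 in DKO, and Cd79b at 12.60 ± 0.55 and 7.89 ± 0.77. H2-Aa was at 12.53 ± 0.43 and 7.81 ± 0.69. Cd74 was chosen after its values were seen.

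**Figure D2:**
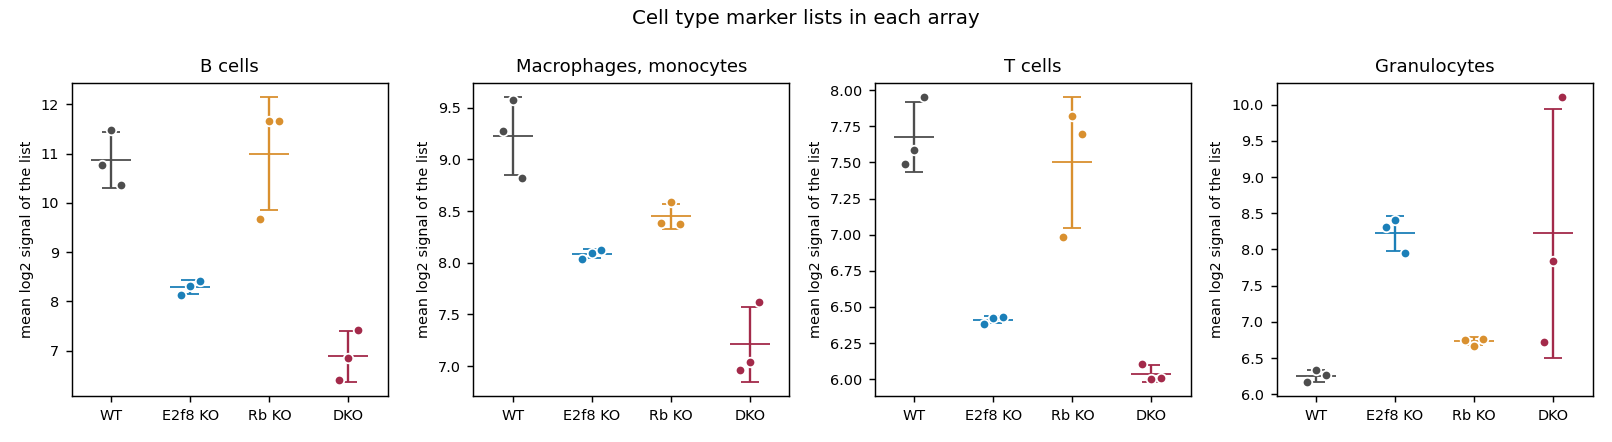
Mean log2 signal of 4 marker lists (y axes) in each array (points), by genotype label (x axes), with the mean and SD of 3 arrays as bars. B cell, macrophage and T cell markers were lower in the arrays labelled E2f8 KO and DKO than in WT, and granulocyte markers were higher.

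The comparison of arrays labelled E2f8 KO with WT asks what the loss of E2f8 does while Rb is present. Of the mitotic genes, 34 of 39 rose and 1 fell (36 and 1 adjusted over the list alone), with a median log2 change of 1.03 (camera adjusted p = 5.28e-11, and adjusted p = 0.530 with an estimated correlation). The spindle checkpoint kinase gene Ttk rose by 1.29 ± 0.27 (SE, n = 3 per group, adjusted p = 0.00543). Cenpf, which encodes a kinetochore protein, rose by 1.26 ± 0.25, and Ect2, needed for cytokinesis, by 1.13 ± 0.21. In the DNA replication list, 25 of 51 rose and 0 fell (27 and 0 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.87e-08, and adjusted p = 0.535 with an estimated correlation). Pold2, of a subunit of DNA polymerase delta, rose by 1.22 ± 0.20, and Gmnn, which limits licensing, by 1.15 ± 0.23. Of the nucleotide synthesis genes, 8 of 21 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00471, and adjusted p = 0.535 with an estimated correlation). Dctpp1 rose by 2.13 ± 0.23 and Mthfd2 by 1.88 ± 0.22. Their median was 0.59, and 0.32 without replicate 3 of WT. The G1/S list had 10 of 20 members that rose and 2 that fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00364, and adjusted p = 0.530 with an estimated correlation). Cyclin E2 (Ccne2) rose by 1.65 ± 0.28 and Cdk2 by 1.46 ± 0.22. Entering the B cell list mean of each array as a covariate gave medians of 0.01 for mitosis, -0.09 for DNA replication, 0.11 for nucleotide synthesis and 0.19 for G1/S, and none of these lists was called. With the macrophage list mean as a second covariate they were 0.42, 0.21, 0.39 and 0.29 (camera adjusted p = 0.0175, 0.166, 0.0575 and 0.0852), so that mitosis stayed called.

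Genes of the p53 response and of terminal erythroid maturation also changed in the arrays labelled E2f8 KO. Of the p53 targets, 12 of 28 rose and 3 fell (14 and 4 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00853, and adjusted p = 0.406 with an estimated correlation). Phlda3, an inhibitor of Akt, rose by 2.75 ± 0.24 (adjusted p = 7.03e-05) and Eda2r, from a mean below the filter level of 5.84 in WT (5.29), by 2.08 ± 0.20, while the antiapoptotic gene Bcl2l1, also on that list, fell by 1.17 ± 0.13. In the late erythroid maturation and autophagy list, 5 of 34 rose and 15 fell (6 and 16 adjusted over the list alone; camera adjusted p = 0.00471, and adjusted p = 0.406 with an estimated correlation). Bpgm, which makes a glycolytic metabolite that lowers the oxygen affinity of hemoglobin, fell by 1.47 ± 0.17. Ube2h, of a ubiquitin enzyme of reticulocytes, fell by 1.36 ± 0.15 and Ube2o fell by 0.95 ± 0.11, whereas Plek2 rose by 2.41 ± 0.19. Of the heat shock and unfolded protein genes, 9 of 26 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00207, and adjusted p = 0.530 with an estimated correlation). Ddit3, a transcription factor gene of the unfolded protein response, rose by 1.90 ± 0.22. The p53, maturation and heat shock lists had medians of 0.38, -0.34 and 0.44 with the B cell covariate and stayed called.

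Leukocyte markers changed beside these groups. Of the B cell markers, 0 of 15 rose and 13 fell (0 and 14 adjusted over the list alone; camera adjusted p = 2.00e-09, and adjusted p = 0.406 with an estimated correlation). Ms4a1 fell by 3.81 ± 0.51, and Cd79a, of the B cell receptor, fell by 3.34 ± 0.48. Macrophage markers had 14 of 19 members that fell (0 and 15 adjusted over the list alone; camera adjusted p = 2.78e-09, and adjusted p = 0.406 with an estimated correlation). Granulocyte markers had 10 of 17 that rose (13 and 0 adjusted over the list alone; camera adjusted p = 4.18e-05, and adjusted p = 0.535 with an estimated correlation). S100a8, of a calcium-binding protein of neutrophils, rose by 3.41 ± 0.78 and Lcn2 by 3.38 ± 0.68. In all, 3388 of 12980 genes changed, 1543 higher and 1845 lower. The balance turned without replicate 1 of WT (1652 higher and 1299 lower), with all probe sets (2414 higher and 2256 lower) and with array weights (3332 higher and 3317 lower). Asking also for a 2-fold change left 486 higher and 995 lower. In 5939 genes (45.8%) the 3 arrays of one group all lay above the 3 of the other, against 10% by chance. That 10% is an average over splits of the arrays. Genes vary together, so that any 1 split can lie away from it, here and below. Limma's count moved by over 1.5 times without replicate 2 of WT (1531 genes) or without replicate 1, 2 or 3 of E2f8 KO (1882, 2033 and 2200 genes). It was 305 with the B cell covariate and 365 with both covariates (226 higher and 139 lower).

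The arrays labelled Rb KO, set against WT to show what the loss of Rb does while E2f8 is present, differed in 1 gene. The histone gene H2bc4 fell by 1.77 ± 0.19 (SE, n = 3 per group, adjusted p = 0.00487). The linker histone genes H1f2 and H1f3 had differences of -1.20 ± 0.23 (adjusted p = 0.114) and -0.74 ± 0.21 (adjusted p = 0.394). E2f1, itself an E2F target, had a difference of 1.06 ± 0.23 (adjusted p = 0.190). At an unadjusted p under 0.05, limma counted 597 genes. Of the 19 macrophage markers, 0 fell over all genes and 14 fell adjusted over the list alone, with a median log2 change of -0.85 (camera adjusted p = 3.04e-26, and adjusted p = 0.0975 with an estimated correlation). Mertk, Adgre1 and Csf1r had differences of -1.46 ± 0.24, -1.21 ± 0.22 and -1.30 ± 0.25 (adjusted p = 0.0827, 0.105 and 0.112). These 3 genes passed the threshold without replicate 3 of WT, at -1.79, -1.45 and -1.54, and without replicate 1 of Rb KO, at -1.40, -1.23 and -1.33. H1f2 and H1f3 did so in the latter case, at -1.42 and -0.92. In the DNA replication list, 0 of 51 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 6.84e-10, and adjusted p = 0.698 with an estimated correlation). The median was 0.06 (camera adjusted p = 0.661) without replicate 1 of Rb KO, 0.58 without replicate 3 of Rb KO, and 0.50 and 0.20 without replicate 1 or 2 of WT. It was 0.36 with the B cell covariate and 0.82 (camera adjusted p = 3.25e-20) with both covariates. The count of genes was 140 without replicate 1 of Rb KO, 35 without replicate 3 of WT, and 0 when only the 6 arrays of the comparison entered the fit. Groups did not overlap in 6.28% of genes, against 10% by chance.

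Relative to other genes, 12 further lists were called in the arrays labelled Rb KO against WT. In parentheses, turned means called in the other direction, and a list whose call was lost may also have changed direction. Red cell membrane had a median of -0.18, with 1 member above and 28 below 0 (camera adjusted p = 9.69e-10, and adjusted p = 0.575 with an estimated correlation). For red cell membrane it was -0.34 without replicate 1 of Rb KO, -0.045 without replicate 3 of Rb KO, -0.12 without replicate 1 of WT and 0.051 with both covariates (call lost). Late maturation had a median of -0.12, with 7 members above and 27 below 0 (camera adjusted p = 4.44e-05, and adjusted p = 0.300 with an estimated correlation). For late maturation it was -0.19 without replicate 1 of Rb KO and -0.069 with both covariates (call lost). Iron handling had a median of -0.12, with 5 members above and 14 below 0 (camera adjusted p = 0.000174, and adjusted p = 0.301 with an estimated correlation). For iron handling it was -0.27 without replicate 1 of Rb KO, -0.028 without replicate 2 of Rb KO, -0.078 without replicate 3 of Rb KO and -0.13 with both covariates (call lost). Heme synthesis had a median of -0.10, with 2 members above and 15 below 0 (camera adjusted p = 0.0107, and adjusted p = 0.698 with an estimated correlation). For heme synthesis it was -0.40 without replicate 1 of Rb KO, -0.056 without replicate 2 of Rb KO (call lost), 0.0084 without replicate 3 of Rb KO (call lost), -0.043 without replicate 1 of WT (call lost), -0.21 without replicate 2 of WT, -0.12 without replicate 3 of WT (call lost) and 0.25 with both covariates (call lost). Globins, with 2 of the 3 measured genes embryonic, had a median of -0.30, with 0 members above and 3 below 0 (camera adjusted p = 0.0384, and adjusted p = 0.575 with an estimated correlation). For globins it was -0.41 without replicate 1 of Rb KO (call lost), -0.21 without replicate 2 of Rb KO (call lost), -0.26 without replicate 3 of Rb KO (call lost), -0.33 without replicate 2 of WT (call lost), -0.040 without replicate 3 of WT (call lost), -0.29 with the B cell covariate (call lost) and -0.50 with both covariates (call lost). Erythroid transcription factors had a median of -0.11, with 7 members above and 19 below 0 (camera adjusted p = 0.00332, and adjusted p = 0.575 with an estimated correlation). For erythroid transcription factors it was -0.30 without replicate 1 of Rb KO, -0.0031 without replicate 3 of Rb KO (call lost), -0.043 without replicate 1 of WT (call lost), -0.18 without replicate 2 of WT and 0.15 with both covariates (call lost). Mitosis had a median of -0.10, with 12 members above and 27 below 0 (camera adjusted p = 0.00525, and adjusted p = 0.809 with an estimated correlation). For mitosis it was -0.36 without replicate 1 of Rb KO, -0.056 without replicate 2 of Rb KO, 0.21 without replicate 3 of Rb KO (turned), 0.064 without replicate 1 of WT (call lost), -0.21 without replicate 2 of WT, -0.043 with the B cell covariate (call lost) and 0.54 with both covariates (turned). DNA damage and replication stress had a median of 0.17, with 27 members above and 10 below 0 (camera adjusted p = 0.00812, and adjusted p = 0.809 with an estimated correlation). For DNA damage and replication stress it was -0.014 without replicate 1 of Rb KO (call lost), 0.38 without replicate 3 of Rb KO, 0.32 without replicate 1 of WT, 0.10 without replicate 2 of WT (call lost), 0.073 without replicate 3 of WT (call lost) and 0.76 with both covariates. Histones had a median of -0.12, with 4 members above and 17 below 0 (camera adjusted p = 0.000146, and adjusted p = 0.698 with an estimated correlation). For histones it was -0.30 without replicate 1 of Rb KO, -0.038 without replicate 2 of Rb KO, -0.014 without replicate 3 of Rb KO, -0.034 without replicate 1 of WT, -0.29 without replicate 2 of WT, -0.023 without replicate 3 of WT (call lost), -0.065 with the B cell covariate and -0.20 with both covariates. Ribosomal proteins had a median of 0.11, with 21 members above and 0 below 0 (camera adjusted p = 0.00958, and adjusted p = 0.736 with an estimated correlation). For ribosomal proteins it was 0.14 without replicate 1 of Rb KO (call lost), 0.053 without replicate 3 of Rb KO (call lost), 0.044 without replicate 3 of WT (call lost) and 0.043 with both covariates (call lost). T cell markers had a median of -0.25, with 3 members above and 8 below 0 (camera adjusted p = 0.0425, and adjusted p = 0.736 with an estimated correlation). For T cell markers it was -0.25 without replicate 3 of DKO (call lost), 0.16 without replicate 1 of Rb KO (call lost), -0.38 without replicate 2 of Rb KO, -0.047 without replicate 3 of WT (call lost) and -0.84 with both covariates. Granulocyte markers had a median of 0.35, with 15 members above and 2 below 0 (camera adjusted p = 0.0412, and adjusted p = 0.809 with an estimated correlation). For granulocyte markers it was 0.31 without replicate 1 of Rb KO (call lost), 0.38 without replicate 3 of Rb KO (call lost), 0.29 without replicate 1 of WT (call lost), 0.42 without replicate 2 of WT (call lost), 0.39 without replicate 3 of WT (call lost), 0.31 with the B cell covariate (call lost) and 2.45 with both covariates.

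In the arrays labelled DKO, compared with WT for the loss of both genes, most of the measured DNA replication genes rose. Of the DNA replication genes, 46 of 51 rose and 0 fell (49 and 0 adjusted over the list alone), with a median log2 change of 1.32 (camera adjusted p = 1.36e-16, and adjusted p = 0.422 with an estimated correlation). Dscc1, of a clamp loader for sister chromatid cohesion, rose by 2.32 ± 0.26 (SE, n = 3 per group, adjusted p = 4.18e-05), and the licensing factor gene Cdt1 rose by 1.72 ± 0.20. For nucleotide synthesis, 15 of 21 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 2.76e-05, and adjusted p = 0.422 with an estimated correlation). Dctpp1 rose by 2.74 ± 0.23 and Rrm2, of ribonucleotide reductase, by 1.37 ± 0.19. In the DNA damage and replication stress list, 27 of 37 rose and 1 fell (29 and 1 adjusted over the list alone; camera adjusted p = 4.49e-09, and adjusted p = 0.422 with an estimated correlation). Clspn, a mediator of checkpoint signalling, rose by 1.86 ± 0.26 and the kinase gene Wee1 by 1.79 ± 0.22. Mitotic genes had a median of 0.89, and 30 of 39 rose and 1 fell (31 and 1 adjusted over the list alone; camera adjusted p = 3.06e-06, and adjusted p = 0.567 with an estimated correlation). In the E2F and pocket protein list, 7 of 13 rose and 3 fell (8 and 3 adjusted over the list alone), though the list was not called (camera adjusted p = 0.109). E2f7, the other atypical E2F gene, rose by 2.24 ± 0.25 and E2f1 by 1.95 ± 0.23. In the same arrays all 15 measured B cell markers fell, with a median log2 change of -4.55. The B cell covariate gave medians of 0.16 for DNA replication (camera adjusted p = 0.987) and 0.43 for nucleotide synthesis (camera adjusted p = 0.316). It gave 0.25 for DNA damage (camera adjusted p = 0.826) and -0.54 for mitosis (camera adjusted p = 1.63e-05, direction turned). With both covariates DNA replication (0.79, camera adjusted p = 0.00280), nucleotide synthesis (1.03, camera adjusted p = 0.0207) and DNA damage (0.98, camera adjusted p = 0.0112) stayed called, and mitosis did not (0.14, camera adjusted p = 0.569, turned relative to other genes).

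In these DKO arrays the p53 target Eda2r, a gene of the TNF receptor family, rose by 4.36 ± 0.20 (adjusted p = 1.99e-07) and Phlda3 by 3.71 ± 0.24. The size is uncertain for Eda2r, whose mean in WT (5.29) was below the filter level of 5.84. Of the p53 targets, 16 of 28 rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 1.19 (camera adjusted p = 0.00032, and adjusted p = 0.287 with an estimated correlation). The death receptor gene Tnfrsf10b rose by 2.28 ± 0.16. Bcl2l1 fell by 1.71 ± 0.13 and the proapoptotic Bcl2l11 rose by 1.47 ± 0.15. The list of apoptosis regulators had 4 members that rose and 6 that fell of 19 and was not called (camera adjusted p = 0.478). Of the heat shock and unfolded protein genes, 14 of 26 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 0.000268, and adjusted p = 0.422 with an estimated correlation). Ddit3 rose by 2.61 ± 0.22 and Chac1 by 2.42 ± 0.33. In the late maturation list, 7 of 34 rose and 14 fell (7 and 19 adjusted over the list alone; camera adjusted p = 0.00131, and adjusted p = 0.287 with an estimated correlation). Bpgm fell by 2.11 ± 0.17, Ube2h fell by 1.85 ± 0.15 and Ube2o fell by 1.48 ± 0.11. The catalase gene Cat fell by 2.08 ± 0.11 and the membrane protein gene Mpp1 fell by 1.68 ± 0.13. The STAT5 target Cish rose by 2.23 ± 0.25 and Erfe, the hormone gene by which erythroblasts lower hepcidin, by 1.74 ± 0.21. The p53, heat shock and maturation lists had medians of 0.69, 0.57 and -0.62 with the B cell covariate and stayed called (camera adjusted p = 0.00926, 0.0300 and 2.95e-05).

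Markers of other cells in the arrays labelled DKO changed beside the erythroid genes. In the B cell list, 0 of 15 rose and 15 fell (0 and 15 adjusted over the list alone; camera adjusted p = 8.03e-12, and adjusted p = 0.287 with an estimated correlation). Ms4a1 fell by 4.92 ± 0.51, H2-Aa, of class II MHC, fell by 4.73 ± 0.35 and Cd79b fell by 4.71 ± 0.46. Macrophage markers had 16 of 19 members that fell (0 and 16 adjusted over the list alone; camera adjusted p = 3.31e-12, and adjusted p = 0.287 with an estimated correlation). Csf1r, of the macrophage growth factor receptor, fell by 3.63 ± 0.25 and Vcam1 fell by 3.00 ± 0.22. T cell markers had 10 of 11 members that fell (0 and 10 adjusted over the list alone; camera adjusted p = 6.89e-07, and adjusted p = 0.287 with an estimated correlation). NK cell markers had 3 of 3 that fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.0177, and adjusted p = 0.287 with an estimated correlation). Dendritic cell markers had 7 of 10 that fell (0 and 7 adjusted over the list alone; camera adjusted p = 6.32e-05, and adjusted p = 0.287 with an estimated correlation). Granulocyte markers had 11 of 17 that rose (15 and 0 adjusted over the list alone; camera adjusted p = 0.00032, and adjusted p = 0.567 with an estimated correlation). S100a8 rose by 3.39 ± 0.78 and S100a9 by 3.25 ± 0.72. Without replicate 3 of DKO the granulocyte median went from 2.05 to 0.95, S100a8 to 2.15 and S100a9 to 2.06. Altogether 4952 genes changed, 2669 higher and 2283 lower. The balance turned without replicate 3 of WT (2209 higher and 2268 lower) and with a 2-fold change asked for as well (1124 higher and 1223 lower). The groups did not overlap in 5961 genes (45.9%, against 10% by chance). The B cell covariate gave medians of -0.77 for T cells, -0.27 for NK cells and -0.42 for dendritic cells, the latter pair no longer called, and 3.90 for granulocytes. Both covariates gave -1.41, -0.88 (not called), -0.50 and 6.72. These values extend slopes found within groups across the distance between WT and DKO, so that their sizes are uncertain. The count was 1109 with the B cell covariate and 766 with both covariates.

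The remaining lists had median log2 changes between -0.33 and 0.48 in the arrays labelled DKO against WT. Of the G1/S regulators, 10 of 20 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0148, and adjusted p = 0.529 with an estimated correlation). Skp2, of a ubiquitin ligase that removes a Cdk inhibitor, rose by 1.98 ± 0.26 and cyclin D1 (Ccnd1) fell by 1.51 ± 0.20. Ribosomal proteins had 8 of 21 members that fell (0 and 9 adjusted over the list alone; camera adjusted p = 0.000476, and adjusted p = 0.529 with an estimated correlation). Interferon response genes had 12 of 26 that fell and 2 that rose (3 and 12 adjusted over the list alone; camera adjusted p = 0.0167, and adjusted p = 0.567 with an estimated correlation). Histone genes had a median of 0.33, and 7 of 21 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0177, and adjusted p = 0.614 with an estimated correlation). They lost the call without replicate 2 of WT (0.29) or replicate 1 of DKO (0.18). Oxidative stress genes had a median of 0.48, and 9 of 17 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0419, and adjusted p = 0.581 with an estimated correlation). Their call was lost without replicate 2 of WT (0.38), replicate 1 of DKO (0.54) or replicate 3 of DKO (0.37). The B cell covariate turned histones (-0.59, camera adjusted p = 1.63e-05) and oxidative stress (-0.14, camera adjusted p = 0.0225). It ended the calls of G1/S (0.020, turned relative to other genes), ribosomal proteins (-0.11) and interferon response (-0.28). Both covariates turned histones (-0.70, camera adjusted p = 0.000175) and ended the calls of oxidative stress (0.22), G1/S (0.39), ribosomal proteins (-0.19) and interferon response (0.46). Of these, oxidative stress and interferon response also turned relative to other genes. Lists of the red cell program were not called: globins (median -0.16 over 3 genes, 2 of them embryonic, camera adjusted p = 0.631), heme synthesis (2 rose and 2 fell of 17, adjusted p = 0.631), iron handling (3 rose and 7 fell of 19, adjusted p = 0.267), membrane proteins (5 rose and 5 fell of 29, adjusted p = 0.993), erythroid transcription factors (6 rose and 4 fell of 26, adjusted p = 0.478) and early progenitor genes (3 rose and 5 fell of 16, adjusted p = 0.274). Neither were those of mitochondria (9 rose and 4 fell of 41, adjusted p = 0.478), glycolysis (3 rose and 5 fell of 22, adjusted p = 0.631), the erythropoietin and STAT5 response (6 rose and 4 fell of 18, adjusted p = 0.229), megakaryocytes (1 rose and 2 fell of 10, adjusted p = 0.809), mast cells (median 0.24 over 3 genes, adjusted p = 0.631) and stromal cells (0 rose and 1 fell of 7, adjusted p = 0.173).

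**Figure D3:**
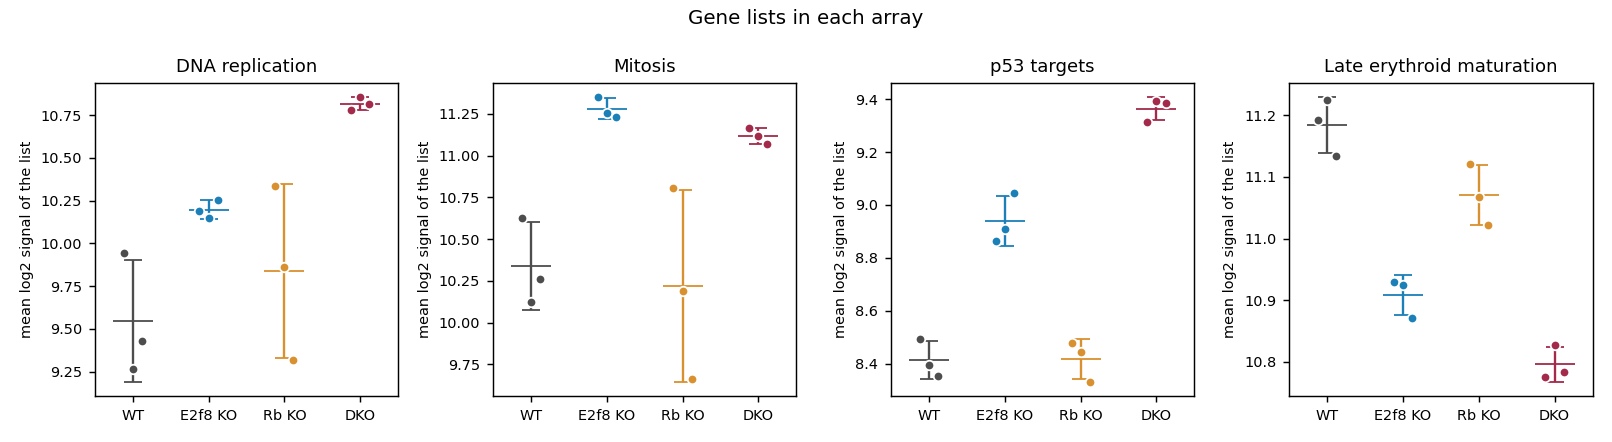
Mean log2 signal of 4 gene lists (y axes) in each array (points), by genotype label (x axes), with the mean and SD of 3 arrays as bars. DNA replication genes stood at 10.78, 10.86 and 10.81 in the arrays labelled DKO and 9.94, 9.27 and 9.43 in WT, and p53 targets at 9.31, 9.39 and 9.39 in DKO and 8.49, 8.40 and 8.35 in WT.

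DKO arrays were also set against arrays labelled Rb KO, for the loss of E2f8 where Rb is lost as well. Eda2r rose by 4.33 ± 0.20 (SE, n = 3 per group, adjusted p = 2.18e-07), Mybl1, a Myb family transcription factor gene, by 3.29 ± 0.31, and Klhl7 by 3.15 ± 0.24. Eda2r had a mean of 5.32 in Rb KO, below the filter level of 5.84, so that the size of its rise is uncertain. In the DNA replication list, 43 of 51 rose and 0 fell (47 and 0 adjusted over the list alone; camera adjusted p = 1.60e-12, and adjusted p = 0.415 with an estimated correlation). Gmnn rose by 1.57 ± 0.23 and Dscc1 by 1.85 ± 0.26. Of the mitosis list, 33 of 39 rose and 1 fell (36 and 1 adjusted over the list alone; camera adjusted p = 8.04e-09, and adjusted p = 0.415 with an estimated correlation). Of the histone genes, 13 of 21 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 2.97e-05, and adjusted p = 0.415 with an estimated correlation). Slbp, on that list for its product that binds histone mRNA, rose by 1.34 ± 0.22. Of the p53 targets, 16 of 28 rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 2.97e-05, and adjusted p = 0.165 with an estimated correlation). Ribosomal protein genes had 14 of 21 members that fell and 0 that rose (0 and 14 adjusted over the list alone; camera adjusted p = 1.13e-05, and adjusted p = 0.415 with an estimated correlation). Rpl5 fell by 0.89 ± 0.15 and Rps14 fell by 0.77 ± 0.12. E2f7 rose by 2.03 ± 0.25, and Tfdp1, whose product pairs with E2Fs, by 1.19 ± 0.23. Of 32 lists, 19 were called in this comparison, and not all are described here. Granulocyte markers, also called, had a median of 1.46, and 2.35 and 0.57 without replicate 1 or 3 of DKO.

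B cell markers fell in the same comparison, in 15 of 15 genes with a median of -4.62 (0 and 15 adjusted over the list alone; camera adjusted p = 2.24e-12, and adjusted p = 0.340 with an estimated correlation). Cr2, of a complement receptor, fell by 4.95 ± 0.55 to a mean below the filter level of 5.84 (5.61) and Ms4a1 fell by 5.22 ± 0.51. Under the B cell covariate the DNA replication median was -0.17, mitosis -0.60 and histones -0.38, each turned in direction. DNA replication was then no longer called (camera adjusted p = 0.0597). The p53 targets stayed called at 0.77 and ribosomal proteins at -0.21. Both covariates gave 0.0031 for DNA replication (camera adjusted p = 0.380), -0.40 for mitosis and -0.35 for histones, with p53 targets (0.78) and ribosomal proteins (-0.29) still called. Over all genes 4819 changed, 2531 higher and 2288 lower, 661 with that covariate and 945 with both. The balance turned without replicate 2 or 3 of DKO (1963 higher and 2018 lower, 1980 higher and 2008 lower), without both low-Xist arrays (1739 higher and 1792 lower) and with a 2-fold change asked for as well (1004 higher and 1164 lower). Groups did not overlap in 43.6% of genes, against 10% by chance.

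Between arrays labelled DKO and E2f8 KO, the comparison for the loss of Rb where E2f8 is lost, fewer genes changed, 308 in all, 224 higher and 84 lower. Klhl7, of a ubiquitin ligase adaptor, rose by 3.74 ± 0.24 (SE, n = 3 per group, adjusted p = 1.04e-05), Mid1 by 2.89 ± 0.28 and Cgas, the sensor of cytosolic DNA, by 2.43 ± 0.30. Klhl7 (5.58) and Cgas (5.72) had means in E2f8 KO below the filter level of 5.84, so that the sizes of their rises are uncertain. The p53 targets Eda2r and Tnfrsf10b rose by 2.28 ± 0.20 and 2.22 ± 0.16, and Pidd1 by 1.47 ± 0.19. Of their list, 4 of 28 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.000359, and adjusted p = 0.289 with an estimated correlation). The STAT5 targets Podxl and Cish rose by 1.60 ± 0.18 and 1.55 ± 0.25, though their list was not called (camera adjusted p = 0.191). Of the DNA replication genes, 7 of 51 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 9.25e-16, and adjusted p = 0.485 with an estimated correlation). Dscc1 rose by 1.55 ± 0.26. Cd36, of a scavenger receptor, fell by 2.48 ± 0.23, Cat fell by 1.09 ± 0.11 and the plasma cell gene Jchain fell by 3.24 ± 0.43. Macrophage markers had 6 of 19 that fell (0 and 15 adjusted over the list alone; camera adjusted p = 2.26e-12, and adjusted p = 0.353 with an estimated correlation), among them Adgre1 (-1.75 ± 0.22). B cell markers had 4 of 15 that fell (0 and 6 adjusted over the list alone; camera adjusted p = 9.65e-08, and adjusted p = 0.485 with an estimated correlation).

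The number of changed genes was 79, 94 and 106 without replicate 1, 2 or 3 of E2f8 KO. It was 90 and 106 without replicate 2 or 3 of DKO, and 712 without replicate 1 of Rb KO, which enters only the shared estimate of the spread. It was 53 without both low-Xist arrays and 1916 with the B cell covariate, under which the DNA replication list (0.19) and the p53 targets (0.21) were no longer called. Both covariates gave 1590 genes, kept the DNA replication call (0.58, camera adjusted p = 0.000339) and ended the p53 call (0.25, camera adjusted p = 0.112). Groups did not overlap in 35.0% of genes, against 10% by chance.

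Mitosis went the other way from DNA replication in DKO against E2f8 KO, and more lists were called. Mitosis had a median of -0.14, with 7 members above and 32 below 0 (camera adjusted p = 0.0388, and adjusted p = 0.888 with an estimated correlation). For mitosis it was -0.14 without replicate 2 of DKO (call lost), -0.12 without replicate 3 of DKO (call lost), -0.11 without replicate 1 of E2f8 KO (call lost), -0.14 without replicate 3 of WT (call lost), -0.68 with the B cell covariate and -0.25 with both covariates. Heme synthesis had a median of -0.13, with 3 members above and 14 below 0 (camera adjusted p = 0.0388, and adjusted p = 0.715 with an estimated correlation). For heme synthesis it was -0.13 without replicate 1 of DKO (call lost), -0.15 without replicate 2 of DKO (call lost), -0.19 without replicate 3 of DKO, -0.12 without replicate 1 of E2f8 KO (call lost), -0.13 without replicate 3 of WT (call lost), -0.52 with the B cell covariate and -0.33 with both covariates. Late maturation had a median of -0.12, with 10 members above and 24 below 0 (camera adjusted p = 0.0182, and adjusted p = 0.485 with an estimated correlation). For late maturation it was -0.32 with the B cell covariate. The E2F and pocket protein family had a median of 0.41, with 8 members above and 5 below 0 (camera adjusted p = 0.0141, and adjusted p = 0.485 with an estimated correlation). For the E2F and pocket protein family it was 0.23 with the B cell covariate (call lost) and 0.44 with both covariates (call lost). Nucleotide synthesis had a median of 0.51, with 19 members above and 2 below 0 (camera adjusted p = 4.79e-05, and adjusted p = 0.485 with an estimated correlation). For nucleotide synthesis it was 0.22 with the B cell covariate (call lost). DNA damage and replication stress had a median of 0.54, with 34 members above and 3 below 0 (camera adjusted p = 8.11e-09, and adjusted p = 0.485 with an estimated correlation). For DNA damage and replication stress it was 0.27 with the B cell covariate (call lost). Heat shock and unfolded protein had a median of 0.17, with 21 members above and 5 below 0 (camera adjusted p = 0.0388, and adjusted p = 0.715 with an estimated correlation). For heat shock and unfolded protein it was 0.091 without replicate 2 of DKO (call lost), 0.13 without replicate 3 of DKO (call lost), 0.037 without replicate 1 of E2f8 KO (call lost), 0.34 without replicate 2 of E2f8 KO, 0.081 without replicate 3 of E2f8 KO (call lost), 0.13 with the B cell covariate (call lost) and 0.44 with both covariates (call lost). T cell markers had a median of -0.32, with 0 members above and 11 below 0 (camera adjusted p = 0.00680, and adjusted p = 0.567 with an estimated correlation). For T cell markers it was -0.065 with the B cell covariate (call lost) and -0.52 with both covariates. Dendritic cell markers had a median of -0.38, with 2 members above and 8 below 0 (camera adjusted p = 0.0351, and adjusted p = 0.485 with an estimated correlation). For dendritic cell markers it was -0.35 without replicate 2 of DKO (call lost), -0.39 without replicate 2 of E2f8 KO (call lost), 0.048 with the B cell covariate (call lost) and -0.042 with both covariates (call lost).

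The interaction asks whether the E2f8 label has another effect with the Rb label than without it. It was called in 10 genes, 7 above and 3 below 0. Klhl7 had an interaction of 3.78 ± 0.33 on the log2 scale (SE, n = 3 per group, adjusted p = 0.000465), and Mid1 of 3.26 ± 0.40. The TNF receptor family genes Tnfrsf10b and Eda2r had interactions of 2.53 ± 0.23 and 2.25 ± 0.28, Fhl1 of 2.06 ± 0.28 and Podxl of 1.82 ± 0.26. Mean signals of Klhl7 were 6.21 in WT, 5.58 in E2f8 KO, 6.17 in Rb KO and 9.32 in DKO. Klhl7 in E2f8 KO, and Eda2r (5.29 and 5.32) and Ephx3 (5.27 and 5.22) in WT and Rb KO, lay below the filter level of 5.84, so that the sizes of their interactions are uncertain. On the other side, Ccng2, which encodes cyclin G2, had -1.67 ± 0.25, Syt14 -1.56 ± 0.23 and Ephx3 -1.44 ± 0.21. The p53 target list had 2 members called above 0 over all genes and 4 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 1.46e-05, and adjusted p = 0.103 with an estimated correlation). This call ended with the B cell covariate (0.27, camera adjusted p = 0.0713) and with both covariates (0.20, camera adjusted p = 0.0632). That median was 0.15 without replicate 1 of WT and 0.11 without replicate 1 of E2f8 KO. The B cell list had a median of -1.41 (camera adjusted p = 9.52e-10, and adjusted p = 0.772 with an estimated correlation), and -2.18 without replicate 1 of Rb KO. With both covariates, of which it is one, it was 0.22 and not called. Klhl7 and Tnfrsf10b were called without any 1 of the 12 arrays. Of the 10 genes, 2 were called without replicate 1 of WT, 5 without replicate 3 of WT, 4 and 6 without replicate 1 or 2 of E2f8 KO, and 4 without replicate 2 of Rb KO. There were 6 and 8 without replicate 2 or 3 of DKO, and 9 without replicate 3 of E2f8 KO or of Rb KO, with adjusted p of at most 0.0943. Over all genes the count was 49 without replicate 1 of Rb KO, where the balance turned (20 above and 29 below 0), 20 without replicate 1 of DKO and 308 with the B cell covariate (345 with both).

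**Figure D4:**
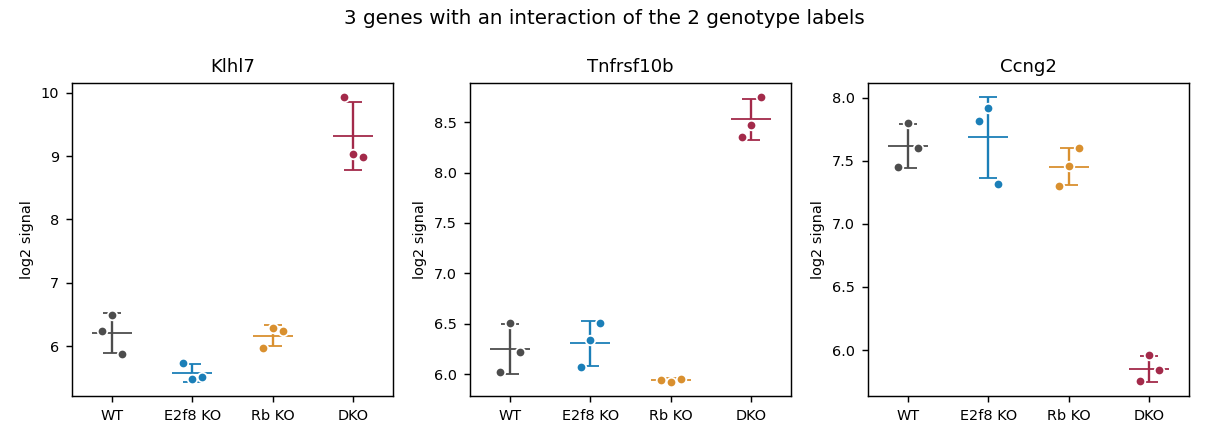
Log2 signal of Klhl7, Tnfrsf10b and Ccng2 (y axes) in each array (points), by genotype label (x axes), with the mean and SD of 3 arrays as bars. The arrays labelled DKO lay above all others for Klhl7 and Tnfrsf10b and below all others for Ccng2.

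The effect of the E2f8 label was correlated between both Rb backgrounds. Across 12980 genes, which are not independent replicates, the log2 change of E2f8 KO against WT and that of DKO against Rb KO had Pearson's r = 0.912 and Spearman's rho = 0.832, with no array in common. Of the genes called in both, 1367 were higher in both, among them Eda2r, Dctpp1 and Plek2, 1543 lower in both, among them Bpgm and Cat, and 4 went opposite ways. Independent lists would share 301 higher and 325 lower genes. The effect of the Rb label, in Rb KO against WT and in DKO against E2f8 KO, had r = 0.399 and rho = 0.335, and r = 0.140 without replicate 1 of Rb KO and 0.225 without replicate 2 of WT. This r is not stable: it was 0.0859 without the 3 arrays that stand apart, 0.329 with the B cell covariate and 0.610 with both covariates.

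**Figure D5:**
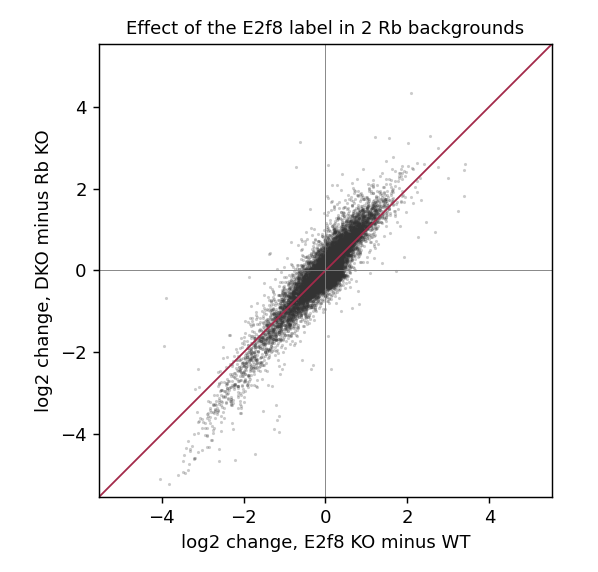
Log2 change of each of 12980 genes (points) in E2f8 KO minus WT (x axis) and DKO minus Rb KO (y axis), with the line of equal change. The points follow the line (Pearson's r = 0.912).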

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

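The comparisons with other splits of the arrays were planned, while the tests of other-cell RNA, sex, exchanged labels and cell shares were chosen after the result was seen. A difference between the effect of the E2f8 label in Rb KO arrays and in arrays without the Rb label drew attention to 10 genes and 10 lists. The interaction was 3.78 on the log2 scale for Klhl7, 3.26 for Mid1, 2.53 for Tnfrsf10b, 2.25 for Eda2r, 2.06 for Fhl1, 1.82 for Podxl, -1.44 for Ephx3, -1.56 for Syt14 and -1.67 for Ccng2, and 1.55 for Snx16, which was chosen after its values were seen. Median interactions of the lists were 0.39 for the E2F and pocket protein family, 0.31 for DNA replication, 0.35 for nucleotide synthesis, 0.35 for DNA damage and replication stress, 0.23 for p53 targets, 0.14 for red cell membrane, -0.13 for ribosomal proteins, 0.080 for histones, 0.16 for the erythropoietin and STAT5 response and -1.41 for B cells. With an estimated correlation none of the 10 lists was called (smallest adjusted p = 0.103). In 6 of 100 groupings of the 12 arrays, the real one included, the interaction reached the real count of 10 genes, and the highest other count was 4167, which points to a structure of the samples. Chance was not excluded for this count. The effect of the E2f8 label can enter the interaction of an uneven draw: the count was reached by 3 of 6 draws with 5 or 1 of the 6 E2f8-labelled arrays on the side of WT and DKO, by 1 of 41 with 4 or 2, and by 1 of 52 with 3, as in the real grouping. List medians that moved by over 1.5 times or lost the call without the array in parentheses are given below, with those under the covariates, of which the B cell list is itself one. Here turned means called in the other direction, and a list whose call was lost may also have changed direction relative to other genes. The E2F family had 0.049 (replicate 3 of Rb KO, call lost), 0.15 (replicate 1 of WT), 0.32 (replicate 3 of WT, call lost), 0.031 (B cell covariate, call lost) and 0.045 (both covariates, call lost). DNA replication had 0.56 (replicate 1 of Rb KO), 0.028 (replicate 3 of Rb KO, call lost), 0.10 (replicate 1 of WT), -0.12 (B cell covariate, call lost) and -0.30 (both covariates, turned). Nucleotide synthesis had 0.55 (replicate 1 of Rb KO), 0.13 (replicate 3 of Rb KO), 0.17 (replicate 1 of WT), 0.20 (B cell covariate, call lost) and 0.039 (both covariates, call lost). DNA damage had 0.58 (replicate 1 of Rb KO), 0.17 (replicate 3 of Rb KO), 0.12 (replicate 1 of WT), 0.011 (B cell covariate, call lost) and -0.19 (both covariates, call lost). The p53 targets had 0.11 (replicate 1 of E2f8 KO), 0.15 (replicate 1 of WT), 0.27 (B cell covariate, call lost) and 0.20 (both covariates, call lost). Ribosomal proteins had -0.10 (replicate 3 of DKO, call lost), -0.21 (replicate 1 of E2f8 KO), -0.10 (replicate 3 of E2f8 KO, call lost), -0.085 (replicate 3 of WT, call lost), -0.047 (B cell covariate, call lost) and -0.076 (both covariates, call lost). The erythropoietin list had -0.056 (replicate 3 of Rb KO), 0.072 (replicate 1 of WT), 0.17 (replicate 3 of WT, call lost), 0.30 (B cell covariate, call lost) and 0.32 (both covariates, call lost). The B cell list had -2.18 (replicate 1 of Rb KO), 0.21 (B cell covariate, call lost) and 0.22 (both covariates, call lost). Red cell membrane had 0.14 (replicate 1 of DKO, call lost), 0.13 (replicate 2 of DKO, call lost), 0.14 (replicate 2 of E2f8 KO, call lost), 0.11 (replicate 3 of E2f8 KO, call lost), 0.31 (replicate 1 of Rb KO), 0.13 (replicate 2 of Rb KO, call lost), -0.013 (replicate 3 of Rb KO, call lost), 0.064 (replicate 1 of WT, call lost), 0.15 (replicate 3 of WT, call lost), -0.18 (B cell covariate, call lost) and -0.28 (both covariates, turned). Histones had 0.081 (replicate 1 of DKO, call lost), 0.12 (replicate 2 of DKO), 0.12 (replicate 1 of E2f8 KO), 0.047 (replicate 2 of E2f8 KO, call lost), 0.14 (replicate 3 of E2f8 KO), 0.37 (replicate 1 of Rb KO), 0.036 (replicate 2 of Rb KO, call lost), -0.016 (replicate 3 of Rb KO, call lost), -0.0012 (replicate 1 of WT), 0.34 (replicate 2 of WT), 0.11 (replicate 3 of WT, call lost), -0.23 (B cell covariate, call lost) and -0.14 (both covariates, call lost). Klhl7 and Tnfrsf10b alone of the 10 genes stayed called without any 1 array.

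For comparisons of 3 against 3 arrays, the 10 possible splits are too few for a share under 0.05. The real split was the only 1 of 10 to reach its own count for E2f8 KO against WT (3388 genes, highest other 0), DKO against WT (4952, highest other 0), DKO against Rb KO (4819, highest other 69) and DKO against E2f8 KO (308, highest other 0), all counted with limma, for which 5004, 5952, 5854 and 2349 genes had an unadjusted p under 0.05 in the real splits. For Rb KO against WT, 2 of 10 splits reached the real count of 1 gene. The other of these, replicates 1 and 3 of WT with replicate 1 of Rb KO against the remaining 3 arrays, called 1841 genes, which points to a structure of the samples within both groups. This split also separated the B cell list means (10.77, 10.36 and 9.67 against 11.49, 11.67 and 11.66). Means of the macrophage and T cell lists overlapped. Whether RNA of other cells gave these calls was not tested.

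DNA replication genes (median 1.32) and p53 targets (median 1.19) were higher in arrays labelled DKO than in WT, and sex is argued against for the former list, since its median was 1.33 without both low-Xist arrays. Less RNA of other cells in the DKO arrays stays open for both: erythroid genes at the same signal level had medians of -0.054 (21 genes, quartiles -0.48 and 0.39) beside DNA replication (quartiles 1.03 and 1.60) and 0.15 (22 genes, quartiles -0.20 and 0.59) beside p53 targets (quartiles -0.20 and 1.72), which speaks against it for the former and decides nothing for the latter. With the B cell covariate the DNA replication call ended (median 0.16, camera adjusted p = 0.987) and the p53 call did not (median 0.69, camera adjusted p = 0.00926), while with B cell and macrophage covariates both held (0.79 and 0.91). These calls use the preset correlation. With an estimated one, and no covariate, no list was called for DKO against WT (smallest camera adjusted p = 0.287). With 1 coefficient per label, the slope on the covariate comes from differences within groups. It is carried over the distance from a B cell list mean of 10.87 in WT to 6.89 in DKO. For DNA replication these fits therefore cannot tell RNA of other cells from an effect of the genotype. Loss of both repressors, raising E2F targets and a p53 response in erythroblasts, may be the source and is a hypothesis that these arrays leave open. With the preset correlation both lists were also called higher in arrays labelled E2f8 KO than in WT (medians 0.63 and 0.39). The pattern is therefore not particular to the DKO arrays, though its medians were larger there.

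Arrays labelled E2f8 KO resembled DKO arrays, and arrays labelled Rb KO resembled WT arrays, with 308 genes called between the former groups and 1 between the latter. These counts depend on the estimate of the spread. They were 712 and 140 without replicate 1 of Rb KO, and 1262 and 0 with only the groups compared. Groups did not overlap in 35.0% and 6.28% of genes, against 10% by chance. An exchange of these labels may be considered, since Rb1 was lower without overlap in arrays labelled E2f8 KO than in those labelled Rb KO, by a log2 difference of -0.71. DKO arrays (11.98 to 12.23) also lay below those labelled Rb KO (12.33 to 12.53). Against WT the fall of Rb1 was called for the labels E2f8 KO and DKO, the groups without Rb if labels were exchanged. It was not called for the label Rb KO, though those arrays too lay below all WT arrays (12.71 to 13.02). The E2f8 probe set cannot decide this, since in DKO arrays, where E2f8 is lost under both assignments, it was higher (13.13, 13.17 and 13.09) than in WT (12.28, 11.70 and 11.88). Without probe positions the exchange and the labels as given cannot be told apart. A different share of RNA of other cells is also open: with the B cell covariate the correlation of the effects of the E2f8 label was 0.847, against 0.912 without it, but the count of E2f8 KO against WT went from 3388 to 305. The fall of that count decides nothing. B cell list means of the WT arrays (10.36 to 11.49) and E2f8 KO arrays (8.14 to 8.42) do not overlap, so the covariate widens the standard error of their difference. A stronger effect of E2f8 loss than of Rb loss in these cells is the biological candidate explanation and was not tested apart from the labels.

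B cell, T cell and macrophage markers were lower in arrays labelled DKO than in WT. RNA of other spleen cells in the WT arrays, despite the sort for Ter119 and CD71, is a candidate explanation that was not decided, since the fall of 100% of the 15 measured B cell markers restates the pattern and names no source of the RNA. Cd74, Cd79b and Vcam1 went from 13.13, 12.60 and 11.48 in WT to 8.59, 7.89 and 8.49 in DKO. A higher share of erythroid cells alike against every other type is argued against by the granulocyte list, whose median rose by 2.05 and by 0.95 without replicate 3 of DKO. In the lowest group, 13 of 15 B cell, 17 of 19 macrophage and 8 of 11 T cell markers still had mean signals above the filter level of 5.84. A change in the spleen of the mutant mice, with fewer lymphocytes and more granulocytes beside the erythroblasts, stays open and was not tested.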

How the results depend on the processing

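The covariate fits and the fits without arrays that stand apart were chosen after the result was seen, and the other alternatives were planned. Of 226 named gene results, 210 were called, and 62 of these kept direction and call under every alternative. The covariate fits are among these alternatives. There, B cell and macrophage markers such as Ebf1 were adjusted for the mean of their own list, so that their losses and turns are partly built in. The effect of the E2f8 label in both backgrounds had r within 0.0463 of the reported value except with a covariate. That margin is a jackknife SE, computed from the fits without 1 array, so those fits are no test of it. For the Rb label that SE (0.361) was nearly as large as r (0.399), so it bounds little: r was 0.0859 without the 3 arrays that stand apart and 0.610 with both covariates. Counts were within 1.5 times of those reported under no filter, centring, the mean of probe sets, no variance trend and the replicate block, and elsewhere with the exceptions below, where the cause was not tested unless it is given.

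Removal of the lowest 60% gave 6 interaction genes, quantile normalization 14 genes for Rb KO against WT, and all probe sets 7398 for DKO against Rb KO, with more features tested. Array weights gave 6649 for E2f8 KO against WT, 101 for Rb KO against WT, 2683 for DKO against E2f8 KO and 59 for the interaction. At an adjusted p under 0.10 there were 11 for Rb KO against WT and 615 for DKO against E2f8 KO, by construction. Asking also for a 2-fold change left 1481 for E2f8 KO against WT, 2347 for DKO against WT, 2168 for DKO against Rb KO and 152 for DKO against E2f8 KO. With only the groups compared, limma called 0 genes for Rb KO against WT (597 had an unadjusted p under 0.05 with all arrays) and 1262 for DKO against E2f8 KO. Residuals of arrays with the same replicate number correlated above 0.1 in 7 of 18 pairs (from -0.379 to 0.570). Arrays with different numbers were not compared, so this cannot decide whether replicate numbers pair the arrays.

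Without 1 array, the lowest and highest counts were 1531 and 4384 for E2f8 KO against WT, 1 and 140 for Rb KO against WT, 3649 and 5621 for DKO against WT, 3423 and 5789 for DKO against Rb KO, 79 and 712 for DKO against E2f8 KO and 2 and 49 for the interaction. The correlations ran from 0.881 to 0.928 for the E2f8 label and from 0.140 to 0.548 for the Rb label. The highest counts and the lowest correlation for the Rb label came without replicate 1 of Rb KO.

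List medians whose direction relative to other genes turned without 1 array had these ranges: DNA damage and replication stress list, Rb KO vs WT, from -0.014 to 0.38, T cells list, Rb KO vs WT, from -0.38 to 0.16, Mitosis list, Rb KO vs WT, from -0.36 to 0.21, and Red cell membrane and surface list, interaction, from -0.013 to 0.31. Of named genes, 27 results lost the call without at least 1 array, as did or turned 26 of 91 list results, and by comparison 2 of 56 called genes for E2f8 KO against WT, 17 of 36 for DKO against E2f8 KO and 8 of 10 for the interaction. Under the settings other than a covariate, the loss of 1 array or the estimated correlation, 45 gene results and 53 list results became weaker and 21 gene results stronger, summed over settings, and 3 list results turned: with array weights, T cells 0.10 (Rb KO against WT), and without the 3 arrays that stand apart, DNA damage and replication stress -0.014 and T cells 0.16 (Rb KO against WT). All 91 list calls were lost with an estimated correlation. Without both low-Xist arrays, 2095 genes were called for E2f8 KO against WT and 53 for DKO against E2f8 KO, with 10 arrays in the fit. Without the 3 arrays that stand apart, 48 were called for Rb KO against WT and 107 for the interaction, 26 above and 81 below 0, so that its balance turned.

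With the B cell covariate the counts were 305 for E2f8 KO against WT, 62 for Rb KO against WT, 1109 for DKO against WT, 661 for DKO against Rb KO, 1916 for DKO against E2f8 KO and 308 for the interaction, and r of the E2f8 label was 0.847. Of the gene results, 104 became weaker and 8 stronger, and of the list results 34 became weaker. Results that turned, for lists relative to other genes, were 11 genes and 20 lists. In E2f8 KO against WT these were Slc2a1 0.22, Fcer2a 0.0023, DNA replication -0.094, Mitosis 0.014, DNA damage and replication stress -0.041 and Histones -0.35. For DKO against WT these were Ebf1 0.23, Ect2 -0.49, Ndc80 -0.49, Slc2a1 1.49, G1/S cyclins and regulators 0.020, Mitosis -0.54, Histones -0.59 and Oxidative stress defence -0.14. Within DKO against Rb KO these were Fcer2a 1.34, Ebf1 0.077, Ndc80 -0.47, H2az1 -0.38, Tal1 -0.11, E2F and pocket protein family -0.092, G1/S cyclins and regulators -0.056, DNA replication -0.17, Mitosis -0.60, DNA damage and replication stress 0.10, Histones -0.38 and Oxidative stress defence -0.22. In DKO against E2f8 KO this was B cells 0.36, the list that is itself the covariate. For the interaction these were DNA replication -0.12, DNA damage and replication stress 0.011, Red cell membrane and surface -0.18 and Histones -0.23.

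Both covariates gave 365 for E2f8 KO against WT, 5 for Rb KO against WT, 766 for DKO against WT, 945 for DKO against Rb KO, 1590 for DKO against E2f8 KO and 345 for the interaction, with r = 0.844 for the E2f8 label. Here 106 gene results became weaker and 1 stronger, 35 list results became weaker, and 9 genes and 21 lists turned. In E2f8 KO against WT these were Slc2a1 0.23, Fcer2a 0.10 and Histones -0.36. For Rb KO against WT these were Mitosis 0.54, Heme biosynthesis 0.25, Erythroid transcription factors 0.15 and Red cell membrane and surface 0.051. Within DKO against WT these were Ebf1 0.43, Ect2 -0.10, Slc2a1 1.49, Mitosis 0.14, Histones -0.70, Oxidative stress defence 0.22 and Interferon response 0.46. In DKO against Rb KO these were Fcer2a 1.40, Ebf1 0.13, Ndc80 -0.28, H2az1 -0.24, E2F and pocket protein family -0.058, G1/S cyclins and regulators -0.038, DNA replication 0.0031, Mitosis -0.40, Histones -0.35 and Oxidative stress defence -0.12. For the interaction these were E2F and pocket protein family 0.045, DNA replication -0.30, Nucleotide synthesis 0.039, DNA damage and replication stress -0.19, Red cell membrane and surface -0.28 and Histones -0.14. Signal over background limits what genes near the filter level of 5.84 can show.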

Other observations

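No further test was run for the values given here, and they were chosen after the result was seen. The principal component with the largest share held 71.3% of the variance and the next 10.4%. On the former, replicate 1 of Rb KO stood at -3.78, apart from replicates 2 and 3 of Rb KO at -57.3 and -66.0 and from the DKO arrays at 57.1, 51.6 and 44.7. The same array had a DNA replication list mean of 10.34 and a mitosis list mean of 10.81, against 9.86 and 10.19 in replicate 2 and 9.32 and 9.66 in replicate 3. No array equalled another, and the lowest correlation between any 2 arrays was 0.928.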
